A study of Mus musculus with 4 samples.

How the data were processed

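The series holds 4 RNA sequencing libraries of sorted CD4+CD8+ thymocytes, 2 WT and 2 KO, grouped by the genotype in the labels. The authors deposited gene counts for each library, and the submitters' processing notes name FastQC 0.11.5, cutadapt 1.17, STAR 2.6.0a, HTSeq 0.6.1, DESeq2 1.24.0 and the genome build GRCm38 (mm10). The strand setting, the annotation release and the settings of these tools are not given in the sources used here, so genes that overlap on either strand may share reads. Several are named as overlapping in the results, and Pfkp, Cyp51, Coro1a, Srsf2, Srsf4, Tap2, Trdc, Sh2d1a, Cd3e, Myb, Gpi1 and Junb overlap other annotated genes too. The authors also deposited an RPKM table with a gene length in bases. Each RPKM value equals the count divided by that length and by the library's total count, within a relative tolerance of 1e-06. The tables hold 53715 genes and no row that names no gene, and symbols are those of the deposited RPKM table. For coordinates, 53620 gene identifiers were matched to GENCODE release 21 for mouse (GRCm38).

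Deposited counts were tested with the edgeR 4.0.16 quasi-likelihood test (robust fit, TMM factors, filterByExpr) in R 4.3.3, with genotype as the only term and no block. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05, with no fold minimum. TMM factors lay between 0.993 and 1.01. Standard errors were taken from the log2 fold change and the quasi-likelihood F statistic. Gene lists with at least 3 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), with an estimated correlation beside it, and with fry. The Benjamini-Hochberg adjustment ran over the 33 lists tested of 34 written. With an estimated correlation camera rests on the few residual degrees of freedom of these libraries, so that form had little power. The groups, the main design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

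Named genes were Srsf1, Irf7 and Il27ra, then the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM, both KO libraries on one side of both WT libraries and an established symbol. Up to 3 called members with the smallest adjusted p from each list with 2 or more calls were added, then a fixed set of reference genes and the 3 most abundant genes of each list of other cell types. Members of short counts outside that rule were named after their values were seen, and so were S1pr1 and Klf2. Some genes that meet the rule are not reported here.

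Each library held 35862730 to 37033180 counts, so 1 count was worth about 0.027 to 0.028 CPM. The tests were tried on simulated data for KO against WT with 2 libraries each and 16588 genes. With 50 genes changed at each size, edgeR called 40% of those changed by 0.5 log2 units, 66% at 1, 90% at 2 and 94% at 3, with 7 false calls among 152. A simulated list shifted by 0.5 log2 units was called and 0 of the others were. Genes were drawn independently there, so this does not test lists whose members move together. In the data the estimated correlation was 0.645 for the cell cycle list. Changes near 0.5 log2 units were thus often missed in the simulation. It changed far fewer genes than the 2408 called in the data, which makes the adjustment stricter, so these shares may not carry over. The calls in the data had a median absolute change of 0.55 log2 units.

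Replicate libraries were compared before use. The chi-square of counts over its degrees of freedom was 17.9 for the WT pair and 20.6 for the KO pair, so no pair was a repeated library, and it was 66.7 to 81.5 between groups. The Y-linked gene Ddx3y had 6368 to 7431 counts in every library and Xist at most 16.

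The alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, and limma on log2 of the RPKM values plus a pseudocount of 0.5 or 0.1. Counts and medians of lists without 1 library come from the version with the filter run again. They are given where a count of 3 or more moved by a factor over 1.5, a rule chosen after the data were seen, and for some other lists. Corrections for gene length and GC content, a crossed pairing, and leaving out each library with the tested genes held fixed were added after the data were seen. Splicing itself was not analysed here, since gene counts do not resolve isoforms. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.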

Results

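RNA sequencing was carried out on CD4+CD8+ double-positive thymocytes, the main stage of T cell development in the thymus, sorted from C57BL/6 mice of 6 to 8 weeks. The wild-type (WT) group and the knockout (KO) group held 2 libraries each. The KO mice carried a floxed Srsf1 gene on both chromosomes and a Cre recombinase driven by Lck, a promoter active in early thymocytes. Srsf1 encodes an SR protein, a class of RNA-binding proteins that act in splice site choice. Reads were counted per gene, and the total counts were 35862730 and 36515358 in the WT libraries and 37033180 and 36389555 in the KO libraries. Levels are given in counts-per-million (CPM), mean ± SD with n = 2 libraries per group. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples only, which may be technical. Within-group library pairs had Pearson correlations of log2 CPM across genes of 0.962 (WT) and 0.960 (KO), and between-group pairs lay from 0.946 to 0.952.

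The targeted gene was lower in both KO libraries. Srsf1 (ENSMUSG00000018379.17, chromosome 11, 88047373 to 88053755, plus strand, GRCm38) had 4821 and 4485 counts in the WT libraries and 1839 and 1772 in the KO libraries. Its level fell from 129 ± 8.87 to 49.2 ± 0.206 CPM, a log2 fold change of -1.39 (SE 0.09, adjusted p = 2.91e-06 by the edgeR quasi-likelihood test). The KO libraries thus kept 0.383 of the WT level in reads over the whole gene, and the labels do not state which part of the gene the loxP sites flank. On log2 of the authors' deposited RPKM values plus 0.5 the log2 fold change was -1.34, with adjusted p = 0.0553 by limma over all genes and 0.00979 over genes with a mean RPKM of at least 1. With 0.1 added it was -1.38 over all genes (adjusted p = 0.0362).

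The first question was which genes differ between KO and WT double-positive thymocytes. Nr4a3, an orphan nuclear receptor induced by T cell receptor signals, fell from 320 ± 15.8 to 56.8 ± 5.79 CPM (log2 fold change -2.49, SE 0.09, adjusted p = 3.27e-08). Foxo1, a transcription factor needed for naive T cell homing genes, fell from 256 ± 2.65 to 84.7 ± 12.1 CPM, and the proapoptotic gene Bcl2l11 (Bim) fell from 672 ± 71.8 to 261 ± 11.8 CPM. In the other direction, Rag1, which encodes a subunit of the recombinase that assembles antigen receptor genes, rose from 2030 ± 99.7 to 3741 ± 101 CPM (log2 fold change 0.88, SE 0.06, adjusted p = 2e-06). The gene Rag1 overlaps an unnamed annotated gene, and without a stated strand setting reads shared between the pair cannot be told apart.

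Of 16588 genes tested, 1100 were higher and 1308 lower in the KO libraries at an adjusted p under 0.05, and 4542 passed an unadjusted p of 0.05. Among the calls that differed by at least 1 log2 unit, 116 were higher and 320 lower. The large increases numbered 208 without WT replicate 1 and 212 without WT replicate 2, against 380 and 260 large decreases. The KO and WT libraries did not overlap in 55.9% of tested genes, where chance gives 33.3% for 2 against 2.

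The lowest fold changes among called genes at 5 CPM or more belonged to Sall3 (log2 fold change -4.29, SE 0.44), Dusp8 (-3.49, SE 0.57), Gfpt2 (-3.25, SE 0.34), Fosl2 (-3.08, SE 0.32), Rasgef1b (-3.0, SE 0.32), Mpzl2 (-2.97, SE 0.49), Fst (-2.95, SE 0.27), Efnb2 (-2.79, SE 0.32), Rbm24 (-2.61, SE 0.15) and Nr4a3. Fosl2, a subunit of the AP-1 transcription factor, went from 169 ± 23.9 to 20 ± 7.96 CPM, and Rbm24, an RNA-binding protein, from 53.7 ± 2.79 to 8.81 ± 0.114 CPM. Without WT replicate 2 the calls of Fosl2 and Dusp8 were lost (adjusted p = 0.134 and 0.386), with log2 fold changes of -2.92 and -3.32. The Dusp8 call was also lost with a filter of at least 1 CPM on average (0.0795), and both were lost with WT replicate 1 paired with KO replicate 2 and the others likewise (0.285 for Dusp8 and 0.23 for Fosl2). The highest belonged to Uaca (2.47, SE 0.36), Gria2 (2.24, SE 0.57), Slc5a9 (2.17, SE 0.23), Col20a1 (2.11, SE 0.34), Nup37 (1.79, SE 0.35), L1cam (1.77, SE 0.22), Nup210l (1.75, SE 0.31), Acrbp (1.64, SE 0.27), Xylb (1.57, SE 0.37) and Kcna2 (1.55, SE 0.15). Most of these increases began from low levels: Uaca went from 1.75 ± 0.262 to 9.74 ± 3.08 CPM, while the potassium channel gene Kcna2 went from 16.1 ± 0.279 to 47.2 ± 3.10 CPM. The call of Gria2 (adjusted p = 0.0428) was lost without KO replicate 1 (0.228) and without KO replicate 2 (0.0855), by DESeq2 (0.0575) and limma-voom (0.0511), with the filter of 1 CPM (0.134), with that pairing (0.483) and with a GC correction (0.053). Col20a1, L1cam and Acrbp overlap other annotated genes.

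**Figure D1:**
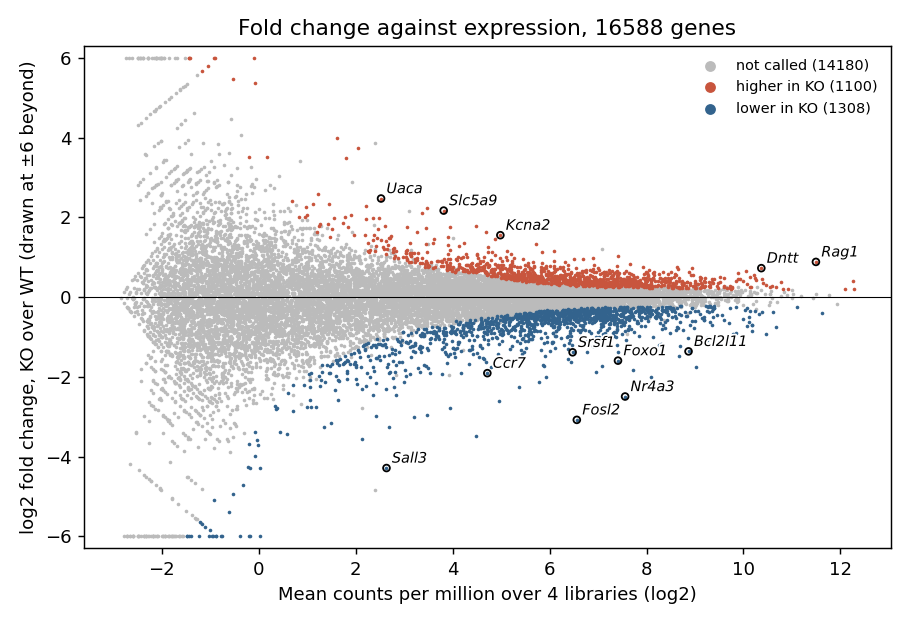
Log2 fold change of KO over WT (vertical axis) against the log2 of the mean CPM over the 4 libraries (horizontal axis), with 1 point per tested gene. Red points mark the 1100 genes called higher in KO, blue points the 1308 called lower and grey points the 14180 not called, and points beyond 6 log2 units are drawn at the edge. Labelled genes are named in the text.

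Genes of the double-positive stage rose more often than they fell. Of 29 tested members of that list, 11 rose, 3 fell and 15 were not called, with 16 higher and 5 lower when adjusted over the list alone. Besides Rag1, Aqp11 rose from 113 ± 5.11 to 229 ± 3.96 CPM (log2 fold change 1.02, SE 0.08), and Dntt, the terminal transferase that adds bases at receptor gene joints, from 996 ± 30 to 1647 ± 82.4 CPM (0.73, SE 0.06). The members that fell were Myb (-0.50), Cd24a (-0.38) and Tcf12 (-0.25), with the Tcf12 call lost without WT replicate 2 (adjusted p = 0.488) or KO replicate 2 (0.0605), with upper-quartile factors (0.0635), a length correction (0.142) or a GC correction (0.0535). Without KO replicate 2, 5 members fell. The list was not called as a set by limma camera (adjusted p = 0.112). Cd8b1 rose (0.54, SE 0.07) and Cd8a rose by less (0.20, SE 0.06, adjusted p = 0.0339). The Cd8a call was lost without WT replicate 1 (0.115), WT replicate 2 (0.219) or KO replicate 1 (0.064). Cd4 (log2 fold change 0.17, SE 0.06, adjusted p = 0.0836) and Cd3e (0.23, SE 0.08, 0.0815) did not pass the test. In the list of the T cell receptor complex and proximal signalling, 8 of 34 members rose and 3 fell (13 and 4 when adjusted over the list alone). Without WT replicate 1, 5 rose. Csk, a kinase that restrains Lck, rose (0.58, SE 0.07).

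Genes of positive selection and later maturation fell more often than they rose. Of 36 tested members, 12 fell, 4 rose and 20 were not called (13 and 4 when adjusted over the list alone), and the set was not called by camera (adjusted p = 0.213). Ccr7, the chemokine receptor that guides selected thymocytes to the medulla, fell from 41.5 ± 3.24 to 11.1 ± 1.05 CPM (log2 fold change -1.91, SE 0.17). Nr4a3 and Foxo1 belong to this list too. S1pr1 (-1.70, SE 0.25) and Klf2 (-0.97, SE 0.17), which act in thymic exit, also fell and were picked after their values were seen. Those that rose included Ms4a6b (0.85), Cd5 (0.41) and Cd27 (0.26), with the Cd27 call lost without WT replicate 1 (adjusted p = 0.111), WT replicate 2 (0.102) or KO replicate 2 (0.0945), or with a length correction (0.0506). Cd69, an early activation marker, had 115 ± 3.97 CPM in WT and 79.8 ± 25.1 CPM in KO (log2 fold change -0.53, SE 0.18, adjusted p = 0.0851). Il7r did not pass the test either (0.84, SE 0.33, adjusted p = 0.122).

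**Figure D2:**
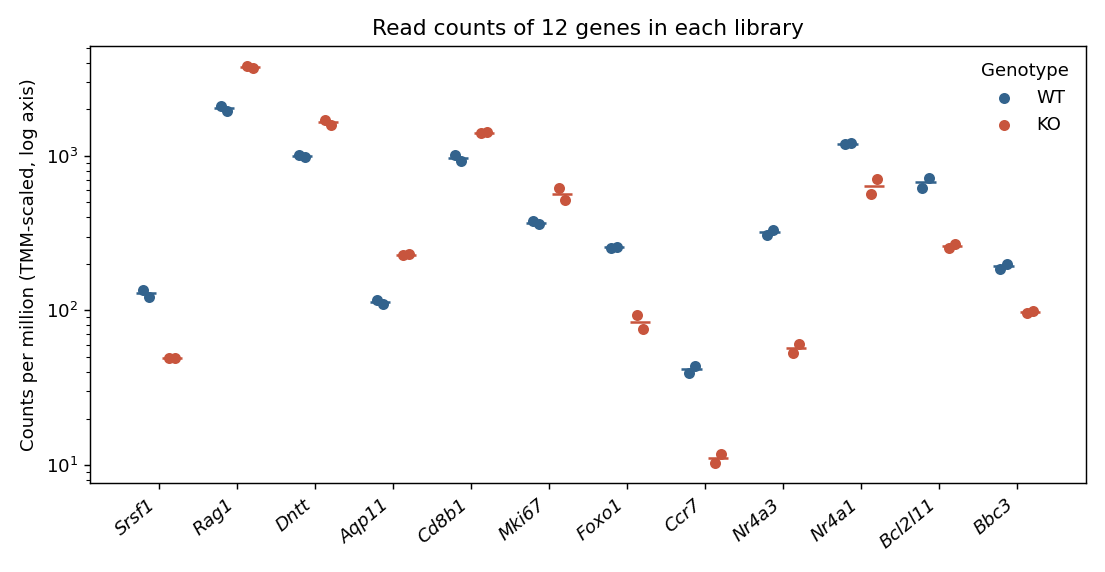
CPM on a log axis for 12 genes, with 1 point per library, WT in blue and KO in red, and a bar at the mean of each group. For each gene both KO libraries lie on the same side of both WT libraries, as for Srsf1 at 129 CPM in WT and 49.2 CPM in KO.

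Of 37 tested apoptosis regulators, 10 fell, 5 rose and 22 were not called (10 and 6 when adjusted over the list alone). Without WT replicate 1, 7 fell and 2 rose. Besides Bcl2l11 (log2 fold change -1.36, SE 0.08), Bbc3 (Puma), another proapoptotic BH3-only gene, fell from 192 ± 8.89 to 97.4 ± 2.19 CPM (-0.98, SE 0.08), and Nr4a1 fell from 1195 ± 18.4 to 636.6 ± 96.0 CPM (-0.91, SE 0.09). Bcl2l1, which encodes the survival factor Bcl-xL, fell by less (-0.32, SE 0.08, adjusted p = 0.016), and its call was lost without WT replicate 2 (0.158). Of 27 tested p53 target genes, 7 fell and 1, Ccng1 (0.50), rose (7 and 3 when adjusted over the list alone). The number of p53 targets that fell was 4 without WT replicate 2, where the Ccng1 call was lost (adjusted p = 0.217). Those that fell included Bbc3, Btg2 (-0.52, SE 0.08) and Plk2 (-0.73, SE 0.16). The median of the p53 list was 0.09 log2 units and its mean -0.14, the median was -0.10 without KO replicate 2, and camera placed the set lower without calling it (adjusted p = 0.66). Trp53 itself rose (0.35, SE 0.09, adjusted p = 0.0166), a call lost without WT replicate 1 (0.0913).

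The type I interferon list and the list of cytokine receptors and JAK-STAT genes were recalled from the study's own focus, so neither is independent of these samples. Of 57 interferon response genes, 5 rose, 2 fell and 50 were not called, with the same counts of 5 and 2 when adjusted over the list alone (camera adjusted p = 0.66). Without WT replicate 1 or without KO replicate 1, 3 rose and 1 fell. Ifi209 (log2 fold change 0.99, SE 0.14) and Stat2 (0.41, SE 0.09) rose and Slfn1 (-2.10, SE 0.49) fell, with the Slfn1 call lost without WT replicate 2 (adjusted p = 0.222). Irf7, a regulator of interferon genes, had 13.9 ± 0.221 CPM in WT and 10.4 ± 1.72 CPM in KO (-0.42, SE 0.23, adjusted p = 0.274). Il27ra, a subunit of the interleukin-27 receptor, had 36.9 ± 3.28 and 40.9 ± 2.17 CPM (0.15, SE 0.13, adjusted p = 0.554). Irf7 and Il27ra each overlap another annotated gene. Of 31 cytokine receptor and JAK-STAT genes, 6 fell and 2 rose (9 and 2 when adjusted over the list alone, camera adjusted p = 0.66). Ifngr2, a chain of the interferon gamma receptor, fell from 149 ± 20 to 68.8 ± 3.17 CPM (-1.11, SE 0.10). Il4ra (-0.63, SE 0.07) and Stat5a (-0.48, SE 0.08) fell as well, and Stat5a overlaps Stat3.

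Cell cycle genes rose more often than they fell. Of 40 tested members, 22 rose, 2 fell (Cdt1 and Mcm4) and 16 were not called (25 and 2 when adjusted over the list alone). The proliferation marker Mki67 rose from 370 ± 9.21 to 567 ± 71.8 CPM (log2 fold change 0.62, SE 0.09), and the mitotic genes Bub1b (0.80, SE 0.11) and Cenpe (0.71, SE 0.11) rose too. The median of the list was 0.52 log2 units, and camera called it higher (adjusted p = 7.29e-05). The call was lost at camera adjusted p = 0.939 with an estimated correlation. That correlation was 0.645, far above the fixed 0.01, so the call assumes members that move almost independently. The number that rose was 14 without KO replicate 1 and 29 without KO replicate 2. The Mcm4 call was lost without WT replicate 2 (adjusted p = 0.18) or KO replicate 2 (0.237), with library size only (0.0518), upper-quartile factors (0.0582), a length correction (0.0548) or a GC correction (0.0598).

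The lists of cytosolic ribosomal proteins and of the nuclear-encoded respiratory chain were the other sets called higher, with small changes. Of 81 ribosomal protein genes, 12 rose and 69 were not called (12 when adjusted over the list alone), and the median was 0.13 log2 units (camera adjusted p = 0.000546). That call was lost at camera adjusted p = 0.939 with an estimated correlation, which was 0.083. With a length correction, several ribosomal protein genes lost their edgeR calls. They were Rplp1 (adjusted p = 0.0509), Rps12 (0.0664), Rps16 (0.0515), Rps18 (0.0713), Rps26 (0.0593) and Rps27a (0.0629). Rplp0 went from 1475 ± 18.3 to 1764 ± 29 CPM (0.26, SE 0.06), and Rpl13a from 16.4 ± 2.15 to 30.9 ± 4.83 CPM (0.92, SE 0.18). The Rplp0 call was lost without WT replicate 2 (adjusted p = 0.0897). The number of ribosomal protein genes that rose was 5 without WT replicate 1, 3 without WT replicate 2 and 19 without KO replicate 2. Of 79 respiratory chain genes, 10 rose and 1 fell (16 and 2 when adjusted over the list alone), with a median of 0.24 log2 units (camera adjusted p = 1.68e-06). The respiratory chain call was lost at camera adjusted p = 0.608 with an estimated correlation (0.0184 unadjusted). That correlation was -0.004, under the fixed 0.01. The loss thus came from the test's few degrees of freedom and not from members that move together. Sdha (0.41, SE 0.08) and Uqcrc2 (0.42, SE 0.09) rose, and the member that fell was Atp5sl (-0.68, SE 0.12), an assembly factor. With a length correction the edgeR calls of Atp5g3 (adjusted p = 0.0731), Cox6b2 (0.0548) and Ndufs7 (0.0528) were lost. The number that rose was 6 without WT replicate 1.

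**Figure D3:**
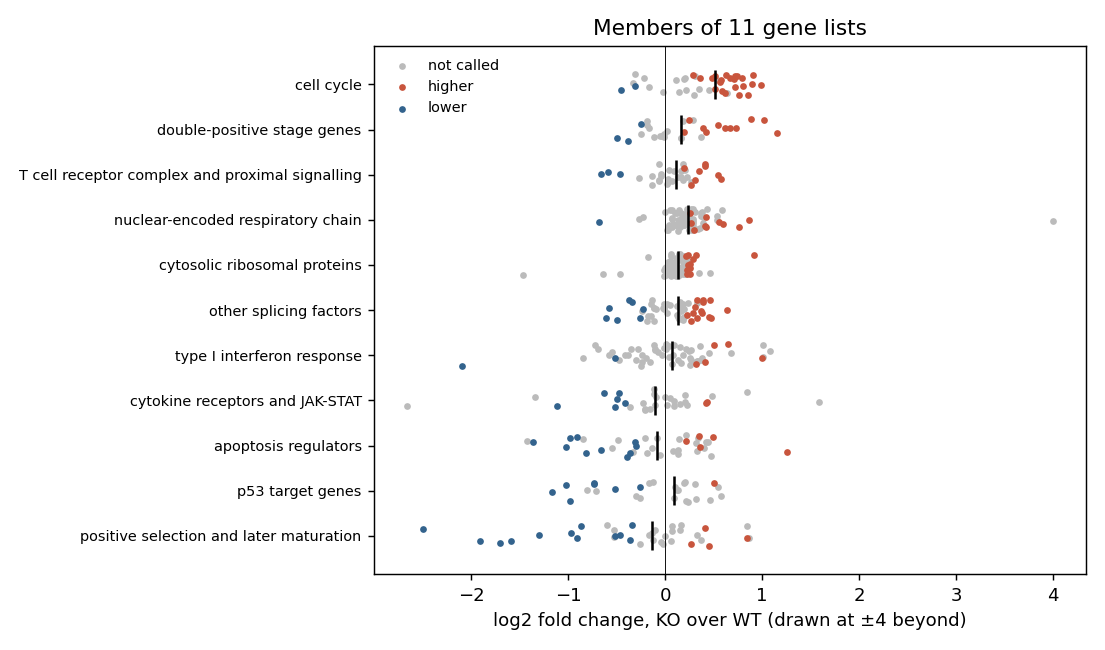
Log2 fold change of KO over WT (horizontal axis) for the tested members of 11 gene lists, with 1 point per gene and a black bar at the list's median. Red points were called higher and blue points lower in KO, grey points were not called, and the cell cycle list has its median at 0.52 log2 units.

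Among the other SR protein genes, Srsf9 (log2 fold change 0.69, SE 0.09) and Srsf6 (0.37, SE 0.07) rose, and the 8 others were not called. Of the 11 in the list, 2 rose and 1, Srsf1, fell, with the same counts when adjusted over the list alone. Srsf2 (-0.43, SE 0.21, adjusted p = 0.273), Srsf3 (-0.09, SE 0.07), Srsf4 (0.15, SE 0.10), Srsf5 (0.12, SE 0.07) and Srsf7 (0.01, SE 0.07) did not pass the test. Of 53 other splicing factors, 14 rose, 7 fell and 32 were not called (20 and 10 when adjusted over the list alone, camera adjusted p = 0.263). The number that rose was 8 without WT replicate 2. Rbm5 rose from 224 ± 7.68 to 348 ± 2.28 CPM (0.64, SE 0.07). The splicing kinase gene Clk3 fell (-0.61, SE 0.07), although Clk3 overlaps Edc3. The SR protein list had a median of 0.06 and a mean of -0.10 log2 units, and camera placed it higher without calling it (adjusted p = 0.811).

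Among metabolic genes, 4 of 20 cholesterol synthesis genes fell and 16 were not called (4 when adjusted over the list alone, camera adjusted p = 0.543). They included the enzyme genes Cyp51 (log2 fold change -0.80) and Sqle (-0.76), and Insig1 (-0.56), a regulator of the pathway. Without KO replicate 2, 2 fell. Of 20 glycolysis genes, 3 fell and 4 rose (3 and 5 when adjusted over the list alone), and 2 rose without WT replicate 1 or without WT replicate 2. Hexokinase 2, Hk2, fell from 28.5 ± 0.0607 to 7.65 ± 2.24 CPM (-1.90, SE 0.22), and Pfkp (-0.85, SE 0.09) and the glucose transporter gene Slc2a1 (-0.79, SE 0.10) fell, whereas Eno1 (0.38), Ldha (0.36), Pdk1 (0.31) and Gpi1 (0.29) rose. The glycolysis list had a median of 0.16 and a mean of -0.12 log2 units, and camera placed it higher without calling it (adjusted p = 0.886). In the endoplasmic reticulum and integrated stress list, 3 of 25 members fell, namely Slc7a11 (-0.72), Sesn2 (-0.74) and Hspa5 (-0.27), and Phgdh (0.33) and Pdia3 (0.26) rose, with the same counts of 3 and 2 when adjusted over the list alone (camera adjusted p = 0.984). The Sqle call was lost without KO replicate 2 (adjusted p = 0.0526), and the Hspa5 call without WT replicate 1 (0.119) or WT replicate 2 (0.0573). Without WT replicate 1 the calls of Ldha (0.0952), Gpi1 (0.0545), Phgdh (0.124) and Pdia3 (0.28) were lost at these adjusted p values. The same held for Pdk1 (0.101) and Gpi1 (0.104) without WT replicate 2 and for Pdia3 (0.0803) without KO replicate 1. In the stress list 5 fell without KO replicate 2.

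Of 18 genes of MHC class I presentation, 6 rose and 1, H2-K1 (log2 fold change -0.33), fell (7 and 2 when adjusted over the list alone, camera adjusted p = 0.237). H2-T23 (0.65, SE 0.08), the immunoproteasome gene Psmb8 (0.55, SE 0.09) and the peptide transporter gene Tap2 (0.35, SE 0.08) rose. The Tap2 call was lost without WT replicate 2 (adjusted p = 0.0606), and the H2-K1 call without WT replicate 2 (0.136) or KO replicate 1 (0.154). H2 genes form a family of similar copies, so their counts are uncertain. Of 18 chemokine receptor and adhesion genes, 3 fell (Ccr7, S1pr1 and Cxcr4) and 3 rose, among them Coro1a and Icam2 (5 and 3 when adjusted over the list alone, camera adjusted p = 0.811). That list had a median of 0.02 and a mean of -0.21 log2 units. The Icam2 call was lost without WT replicate 1 (adjusted p = 0.0704), WT replicate 2 (0.143) or KO replicate 1 (0.0837). Cxcr4 went from 249 ± 8.86 to 144 ± 19.9 CPM (-0.79, SE 0.10). Of 15 genes of the earlier double-negative stage, Notch3 (0.97, SE 0.12) and Ptcra (0.67, SE 0.21) rose and Hes1 (-1.32, SE 0.30) fell, with the same counts of 2 and 1 when adjusted over the list alone. Over all 15 the median was -0.76 and the mean -0.42 log2 units, and camera placed the list lower without calling it (adjusted p = 0.66). With a filter of at least 1 CPM on average 10 members were left, with a median of 0.13. The Ptcra call was lost without WT replicate 1 (0.283) and without KO replicate 2 (0.125), with library size only (0.0501), a length correction (0.0664) or a GC correction (0.0507), and the Hes1 call without WT replicate 2 (0.0617). Of 44 tested T cell receptor alpha V and J segments in 4 lists, edgeR called 0, while 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The median log2 fold changes were 0.45 for J segments used early, -0.29 for J segments used late, -0.11 for V segments near J and -0.10 for V segments far from J, with camera adjusted p values of 0.543, 0.237, 0.66 and 0.936 and 0 calls in each when adjusted over the list alone. Camera and the mean placed the V segments near J higher, against their median. For the V segments far from J, the mean was 0.01 log2 units, against their median and camera. These medians depended on single libraries. The median of the early J segments was 0.08 without KO replicate 1 and -0.0038 without KO replicate 2, and that of the late J segments was -0.12 without WT replicate 2. For the V segments near J it was 0.11 without WT replicate 1, 0.30 without WT replicate 2, 0.14 without KO replicate 1 and -0.21 without KO replicate 2. For the V segments far from J it ran from -0.74 without WT replicate 1 to 0.73 without KO replicate 2.

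Markers of other cell types were measured beside these groups. In the B cell list, Ighm rose from 223 ± 4.43 to 341 ± 2.29 CPM and Cd79b from 8.96 ± 1.94 to 16.7 ± 1.64 CPM, while Igkc had 3.0 ± 0.884 and 3.20 ± 0.103 CPM, and 9 of 11 members were not called (camera adjusted p = 0.239). In the dendritic cell list of 10, Cd74 (log2 fold change -0.99) and H2-Aa (-1.25) fell and Cst3 (0.37) rose (camera adjusted p = 0.327). The Cd74 and H2-Aa calls were lost without WT replicate 2 (0.109 and 0.156). In the macrophage list of 15, Ctss fell from 6.28 ± 2.08 to 2.23 ± 0.878 CPM, a call lost without WT replicate 2 (0.24) and when adjusted over the list alone, and Apoe had 46.4 ± 1.16 and 44.9 ± 11.3 CPM (camera adjusted p = 0.936). In the gamma-delta T cell list of 10, Trdc rose (0.59, SE 0.14) and Maf fell (-0.96, SE 0.18), with camera adjusted p = 0.239. In the innate-like T cell list of 15, Sh2d1a (0.63) and Slamf6 (0.45) rose and Slamf1 (-0.59) fell (camera adjusted p = 0.989). The calls of Cd79b (adjusted p = 0.0976 without WT replicate 2 and 0.0744 without KO replicate 2), Cst3 (0.167 without WT replicate 1, 0.0537 without WT replicate 2 0.207 without KO replicate 2 and 0.0778 with a length correction) and Trdc (0.077 without WT replicate 1) were lost too. Without KO replicate 1 the Ctss and H2-Aa calls were lost (0.127 and 0.193). The macrophage list had a median of -0.05 and a mean of 0.32 log2 units and the innate-like list 0.04 and -0.57, and camera placed both higher. Adjusted over the list alone, 2 B cell, 3 dendritic, 2 gamma-delta and 4 innate-like genes passed. Of 17 tested granulocyte, erythroid, thymic epithelial, fibroblast and endothelial markers edgeR called 0, with 2 at an unadjusted p under 0.05, 1 call by DESeq2 and 1 by limma-voom. Camera adjusted p values were 0.666 for the erythroid, 0.197 for the epithelial and 0.811 for the fibroblast and endothelial list, and the granulocyte list had 1 tested gene, Ngp, at 0.400 ± 0.0905 CPM in WT and 0 counts in KO. Adjusted over the list alone, Ngp passed, as its list held 1 test.

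Lists that bear on RNA quality were also tested. Of 23 immediate early and heat shock genes, 4 fell, namely Fosl2, Ier2 (log2 fold change -0.58), Btg2 and Jund (-0.49), with the same count of 4 when adjusted over the list alone. These counts depended on single libraries: 7 rose and 5 fell without KO replicate 1, 0 rose and 7 fell without KO replicate 2, and 2 rose and 5 fell without WT replicate 1. The median of that list was 0.02 and its mean -0.28 log2 units, and the median lay between -0.12 and 0.12 when single libraries were left out. Camera placed it lower without calling it (adjusted p = 0.66). Of 12 mitochondrially encoded protein genes, mt-Co1 (0.19, SE 0.05) rose, and 1 passed when adjusted over the list alone (camera adjusted p = 0.702). The mt-Co1 call was lost without WT replicate 1 (adjusted p = 0.0827), WT replicate 2 (0.178) or KO replicate 1 (0.0817), or with a length correction (0.0771). Of 52 histone genes, Hist1h4i (0.78) and Hist2h2be (0.87) rose and Hist1h4c (-4.94, SE 1.23) fell, from 1.35 to 0.0407 CPM, and when adjusted over the list alone 0 passed (camera adjusted p = 0.66). The Hist1h4c and Hist1h4i calls were lost without WT replicate 2 (adjusted p = 0.119 and 0.141), and the Hist2h2be call without WT replicate 1 (0.0899) or KO replicate 1 (0.382). Hist1h4c was not called by limma-voom either (0.14), and DESeq2 gave it no adjusted p. Histone genes are near-identical copies, so these values are uncertain. Mitochondrial transcripts took 1.28% and 1.34% of counts in the WT libraries and 1.37% and 1.252% in the KO libraries.

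Over the 33 lists tested, camera called 3, all higher, and with an estimated correlation it called 0, where 1 list had an unadjusted p under 0.05. Few lists could pass in that form, so its 0 does not argue against the respiratory chain call (estimated correlation -0.004). The cell cycle and ribosomal protein lists had estimated correlations of 0.645 and 0.083, above the fixed 0.01. Their camera calls thus rest on the fixed value. By fry, which tests whether a set moves one way on balance, 2 lists passed, the respiratory chain and the J segments used early. The cell cycle and ribosomal protein lists did not (fry adjusted p = 0.321 and 0.123). The mixed test of fry, which takes either direction, passed 27. Unlike camera, fry does not compare a list with the other genes. The mixed test thus passed even the 4 T cell receptor alpha lists, in which edgeR called 0 genes.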

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

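The length and GC corrections, the crossed pairing and the fits with tested genes held fixed were chosen after the data were seen. Across the other scaling factors and filters, DESeq2 and limma-voom, calls numbered 2391 to 2976 against 2408, and no named gene reversed in any alternative. On log2 of RPKM plus 0.5 with no filter, limma called 0 genes (0 higher, 0 lower), although 4063 passed an unadjusted p of 0.05. Srsf1 there had a log2 fold change of -1.34 (adjusted p = 0.0553), against -1.45 to -1.31 in the alternative fits on counts, where the largest adjusted p was 4.92e-06. With a pseudocount of 0.1 limma called 82 genes (22 higher, 60 lower), and with a mean RPKM of at least 1 it called 1200 (538 higher, 662 lower). The cause was not tested. A minimum of 1 log2 unit left 436 genes (116 higher, 320 lower), and an adjusted p under 0.01 left 1147 (456 higher, 691 lower), since both are stricter by construction. Of the gene lists, camera called 6 with DESeq2 statistics, 7 with limma-voom and 0 with an estimated correlation, against 3. The cause was not tested for DESeq2 and limma-voom. The form with an estimated correlation has few degrees of freedom, and it took higher correlations for the cell cycle and ribosomal protein lists. The double-positive list was called higher and the maturation list lower with both DESeq2 and limma-voom.

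Leaving out each library in turn gave 1980 to 2697 calls with the filter run again on the remaining 3 libraries, and the lone library was assumed to vary like the other group. That version was run first. Holding the tested genes at the 16588 of the 4-library filter was tried after its counts were seen, and gave 1760 to 2383 calls. The 2 versions disagreed on some calls: without WT replicate 1, Fosl2 and Dusp8 kept their calls in the first and lost them in the second (adjusted p = 0.189 and 0.35). Without WT replicate 2, the ribosomal protein list had adjusted p = 0.0316 in the first and 0.0544 in the second. In the first version 5, 5, 8 and 16 named genes lost their calls without KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 2.

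With the replicate number as a block, 2809 genes were called, 1304 higher and 1505 lower, and no named call was lost. The labels do not say that the numbers pair the libraries. Deviations of same-numbered libraries from their group means had a correlation across genes of -0.0391, and of -0.243 over the 6966 genes at 20 CPM or more. The crossed pairing called 3249 genes, 1554 higher and 1695 lower, and lost the calls of Dusp8, Fosl2 and Gria2 (adjusted p = 0.285, 0.23 and 0.483). Both correlations are negative, and WT replicate 2 and KO replicate 1 both had more ribosomal RNA counts, so the crossed pairing cannot be set aside.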

Other observations

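The tests of cells of other stages, of tissue handling and of the chromosome segment around Srsf1 were chosen after the results were seen. So were the members of the cAMP and strong-signal lists and the test outside the immediate early list. Members counted as seen were left out of the test of each list. Il7r and Cd69, whose values are given above, were still kept, in the glucocorticoid and strong-signal lists. Members of the immediate early list tested above were kept too, 5 in the cAMP, 2 in the glucocorticoid and 1 in the strong-signal list. The tests on members not seen before were therefore not free of earlier results.

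Genes known to respond to cAMP formed a group not described above. Of 28 tested members, 18 fell and 10 were not called. Pde4d, a phosphodiesterase that degrades cAMP, fell from 805 to 239 CPM (log2 fold change -1.75, SE 0.07, edgeR adjusted p = 3.27e-08). The nuclear receptor genes Nr4a1, Nr4a2 (-1.19, SE 0.10) and Nr4a3, the kinase gene Sik1 (-0.91, SE 0.08), Crem (-1.22, SE 0.18) and Irs2 (-1.02, SE 0.09) fell as well, while Fos (0.29, SE 0.30), Junb (-0.30, SE 0.19) and Cited2 (0.01, SE 0.08) did not pass the test. A hypothesis is that cAMP-responsive genes may be lower as a set in the KO libraries. Among the 19 members not seen before the test, 9 fell and the median was -0.77 log2 units. Over these members limma camera gave adjusted p = 4.11e-05 over the 3 lists of this section (1.37e-05 unadjusted). The call was lost at adjusted p = 0.606 with an estimated correlation (0.213 unadjusted). That form of camera has little power here, while the value of 4.11e-05 assumes a correlation of only 0.01. Low power and members that move together were not told apart as causes of that loss. Several members also respond to T cell receptor signals. The list shares 8 members with the immediate early and heat shock list, among them Fosl2, Ier2 and Btg2, which fell, and Fos, Fosb (SE 0.47) and Junb, whose levels varied between libraries. Over the 14 unseen members outside that list, 9 fell, with a median of -0.80 log2 units and camera adjusted p = 1.45e-05 (0.411 with an estimated correlation). Without single libraries the unadjusted camera p of the 19 members lay between 2.55e-06 and 0.000689. Tissue handling can move such genes too and is left open below, so the stimulus and handling both stay open.

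Other lists gave less. Of 16 tested glucocorticoid-responsive genes 6 fell and 1, Fkbp5 (0.29), rose, a call lost without WT replicate 1 (adjusted p = 0.215) or KO replicate 2 (0.0607). On the 14 members not seen before, limma camera gave 0.151 before and after adjustment, against unadjusted values of 0.0144 with DESeq2 statistics, 0.0483 with limma-voom and 0.273 with the replicate block, and of 0.061 to 0.507 without single libraries. Of 22 genes of a strong T cell receptor signal 7 fell and 2, Cd5 and Pdcd1 (1.36), rose, with the Pdcd1 call lost without KO replicate 2 (adjusted p = 0.294). Without that library 12 fell and 1 rose. On the 18 members not seen before, limma camera gave adjusted p = 0.151 (0.116 unadjusted), against unadjusted values of 0.0131 with DESeq2 statistics, 0.0149 with limma-voom and 0.17 with the replicate block. Without single libraries they were 0.085 (WT replicate 1), 0.338 (WT replicate 2), 0.873 (KO replicate 1, median -0.04 log2 units) and 0.0153 (KO replicate 2, median -0.44). Outside the immediate early list, camera gave adjusted p = 0.0825 for both lists. An unadjusted value of 0.05 or more had been set in advance as evidence against each hypothesis, but it does not exclude a small shift, so both stay open.

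Of 36 tested genes of later maturation 12 fell and 4 rose, and the set was not called (camera adjusted p = 0.213). A trend with gene length or GC content was argued against, since 100% of the lower calls were still lower and called after a length correction and 100% after a GC correction. Fewer mature or selected cells in the KO sort could lower the 12 and cannot be told apart from an effect of Srsf1 loss within cells. The 4 members that rose do not exclude it, since they may have another cause. The Cd27 call among them was lost without WT replicate 1, WT replicate 2 or KO replicate 2. Its log2 fold change stayed at 0.27, 0.27 and 0.20 in these fits. The gate of the sort is not described in the sources used here.

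Large decreases outnumbered large increases by 320 to 116, a ratio of 2.76. The ratio was 2.66 with a length correction and 2.56 with a GC correction (2.655 and 2.562 before rounding), which argues against either trend as its whole cause. Over calls of any size, the excess of 1308 lower over 1100 higher did shrink. With a length correction 1208 were lower and 1199 higher, and with a GC correction 1251 and 1205. The ratio of large calls is the one followed below. It depended on the WT libraries: it was 1.83 without WT replicate 1 and 1.23 without WT replicate 2, or 1.96 and 1.33 with the tested genes held fixed. Tissue handling could lower immediate early and heat shock genes, but their median was 0.0213 log2 units, with 10 of 23 members below 0 and an SD of 0.78. Without KO replicate 1, 7 of them rose and 5 fell, and without KO replicate 2, 0 rose and 7 fell. The bound of -0.50 set for that test lies within that SD. The rule as written used the standard error of the median instead (0.20). By that rule the median lies above the bound, which argues against a fall of the list as a whole. The SD was taken as the wider measure, and the test was chosen after the results were seen. Handling therefore cannot be told apart from an effect of genotype here.

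Several called genes lie near Srsf1 on chromosome 11, among them Mks1 (log2 fold change -1.90, SE 0.51) and Ska2 (1.51, SE 0.21), both picked after their values were seen. A segment of another strain carried along with the targeted allele could change such neighbours. Within 10 Mb of Srsf1 35 of 257 tested genes were called (13.6%), against 14.5% elsewhere. The odds ratio was 0.927 (95% interval 0.628 to 1.33, Fisher's exact p = 0.789), which argues against an excess of calls of any size in that window. Calls of at least 1 log2 unit, such as Mks1 and Ska2, were not tested apart. An excess of large changes near Srsf1 thus stays open, as does a change of single neighbours.

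Transcripts annotated as ribosomal RNA took 0.0931% of counts in WT replicate 2 and 0.0682% in KO replicate 1, against 0.0141% in WT replicate 1 and 0.0138% in KO replicate 2.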
